A study of Mus musculus with 8 samples.

How the data were processed

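Single-nucleus RNA sequencing was available for 8 libraries of mouse hippocampus, 4 labelled PBS treatment and 4 labelled USCs treatment. PBS is phosphate buffered saline; the labels do not spell out USCs, give no age, sex, dose or time after treatment, and do not say whether each library came from 1 mouse. Libraries are called PBS 1 to 4 and USCs 1 to 4 after the numbers in their titles. Per the labels' protocols, nuclei were released from frozen tissue in a homogeniser with a mild detergent, filtered, spun down and loaded on a 10x Genomics chip with the 3' kit. Per the file headers, the matrices were written by Cell Ranger 7.0.1 and hold whole numbers. The deposited values are raw UMI counts per gene and nucleus barcode, which the authors aligned to the mouse build mm10 per the submitters' processing notes. The annotation release, the treatment of introns, the strand setting and any filter after the calling of nuclei are not stated there. Every library listed the same genes, and 32235 of the 32285 gene identifiers were found in the GENCODE annotation of GRCm38, from which positions were taken.

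The files held 67291 barcodes. Totals per library ran from 52654255 UMIs in USCs 4 to 102319067 in PBS 4, and the median per barcode from 5031.5 to 6461. A nucleus was kept with at least 500 genes and at most 5% of UMIs from mitochondrially encoded genes, which left out 2104 barcodes under the minimum of genes and 172 over the mitochondrial maximum. Scrublet in scanpy 1.11.5 scored doublets in each library, and the highest scores were marked at 0.8% per 1000 nuclei, which marked 4546 of 65124 nuclei. Counts were scaled to 10000 per nucleus and log-transformed, 2500 variable genes and 40 principal components were taken, and nuclei were grouped by the Leiden method at resolution 1 from 20 neighbours, without use of the treatment label. Of 35 clusters, 23 took a class name from fixed marker genes, 9 stayed unnamed and 3 were left out as doublets, which left 59564 nuclei in named or unnamed clusters. A cluster took a name when at least 3 markers were found in at least 10% of its nuclei and at least 1 higher on the log2 scale than in other nuclei, and markers of that class led its top 10 genes. A cluster was left out as doublets when over 40% of its nuclei were marked. This percentage was set after the clusters had been seen, and it left out 1 cluster without a class name (1.01% of PBS and 0.492% of USCs nuclei), 1 with microglial markers (0.976% and 0.659%) and 1 with oligodendrocyte markers (0.391% and 0.184%). Names are class-like groups of nuclei, written without that ending.

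UMI counts were summed per library and class, and over all nuclei used. A class was tested where at least 3 libraries per group had at least 20 nuclei of it. Genes were compared with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test with TMM scaling, the default filter on low counts and Benjamini-Hochberg adjustment within the class, with a threshold of 0.05 on the adjusted p. Values per library are CPM, UMIs scaled by the library total in the usual way, computed from the deposited counts. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, for lists with at least 5 genes tested, with adjustment over the lists of a class; 34 lists were fixed. Beside it, the same test was run with a correlation estimated for each list. Shares of classes were compared by an exact two-sided permutation test over the 70 assignments of libraries, whose smallest p is 0.0286, with adjustment over 14 classes. The smallest adjusted p that 1 class alone could reach there is 0.4.

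The tests, the filter on nuclei, the markers, the lists, the rule for named genes and all alternatives not said to be added were chosen before the data were examined. The rule names, in each class with a gene called, the 5 largest rises and 5 largest falls (10 and 10 in the class with most calls) among called genes with an average log2 CPM of at least 3, no overlap between groups and a symbol that is not a predicted gene. It adds up to 4 called members of each list, the 3 smallest p of a class with no call, and a few genes whatever their result. The text names a part of these, and some are not reported here. Fos in DG granule neurons and Cst7 in microglia were under the filter on low counts and were not tested.

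Alternatives were DESeq2 1.42.0, size factors of DESeq2 in edgeR, no filter on low counts, doublets kept, at least 1000 genes per nucleus, resolution 2, counts thinned to equal depth, leaving out genes whose CPM over all other nuclei was over 10 times that in the class, the replicate number as a block, a centred log-ratio of shares with 0.5 added to counts, and each library left out in turn. Sex as a covariate was not run, because all 8 libraries carried Xist (1233.51 to 2355.53 CPM) and none had over 0.247 CPM of a Y-linked gene. Chosen after the data had been seen were the microglial cluster kept that had many marked nuclei, limma voom with a quality weight per library, and the estimated correlation without PBS 4.

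The gene and list tests were tested on simulated counts with the means, library sizes and spread of the libraries and 200 genes changed in each of 5 draws. In DG granule neurons (15125 genes), 20% of genes changed 1.5-fold, 62.1% of those changed 2-fold and 91.2% of those changed 4-fold were recovered, and 4.95% of calls were false. In microglia (6900 genes) these were 9.55%, 49.3%, 88.8% and 3.35%, and over all nuclei (19722 genes) 17.9%, 59.1%, 88.8% and 4.84%. A list raised as a whole was called in 5 of 5 draws in each. Other splits of the 8 libraries called 0 genes there but up to 16, 16 and 19 lists. The draws thus do not vouch for list calls. A library apart like PBS 4 was not tested.

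The labels do not say whether reads were counted by strand, so genes that overlap an annotated gene on the other strand are uncertain and are named as such. Unnamed clusters were not used for gene tests, and DG mossy cells, fibroblasts, perivascular macrophages and choroid plexus epithelium held too few nuclei for one.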

Results

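Nuclei of mouse hippocampus were profiled from 4 libraries of the PBS group and 4 of the USCs group, and the comparison asks how the hippocampus differed between the treatments, in a series on hippocampal aging whose labels give no age. The files held 6727 to 14175 barcodes per library, with 52654255 to 102319067 UMIs per library. PBS 4 had the most UMIs in total and the most barcodes, but a median of 5998 UMIs per barcode, within the 5031.5 to 6461 of the others. In the classes whose genes were tested its median UMIs per nucleus were the lowest of the 8 libraries (7508 in CA1 against 8881 to 10628, 943 in microglia against 1271 to 1953), except in GABA interneurons. Neurons of the dentate gyrus (DG), CA1 and CA2/CA3, interneurons, microglia, oligodendrocytes and 8 further classes were recognised from their markers. Values are means ± SD of CPM over n = 4 libraries per group unless said otherwise, and p-values rest on libraries, of which the labels do not say whether each is 1 mouse.

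No class of nuclei changed its share past the threshold. DG granule neurons made up 26.0% ± 6.73 (SD, n = 4) of nuclei in PBS and 24.997% ± 5.43 in USCs libraries. Oligodendrocytes, the cells that make myelin, made up 15.7% ± 4.59 and 19.0% ± 2.43, CA1 pyramidal neurons 14.05% ± 1.68 and 12.7% ± 1.62, and microglia, the resident immune cells, 3.03% ± 0.599 and 3.60% ± 0.537. GABA interneurons made up 7.83% ± 2.00 and 6.47% ± 1.24, CA2/CA3 pyramidal neurons 5.27% ± 1.77 and 4.40% ± 0.9005, and subicular or cortical excitatory neurons 7.66% ± 1.25 and 6.58% ± 2.34. Astrocytes made up 1.90% ± 0.766 and 1.29% ± 0.338, and oligodendrocyte precursors 2.11% ± 0.369 and 1.70% ± 0.242. The other 5 classes each held under 1% of nuclei, Cajal-Retzius neurons among them at 0.505% ± 0.105 and 0.447% ± 0.0746. The lowest adjusted p over the 14 classes was 0.56 by the exact permutation test. Oligodendrocytes lay mostly in cluster 8 in PBS 1, in cluster 33 in PBS 2 and PBS 3, and in cluster 14 in PBS 4 and the USCs libraries.

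**Figure D1:**
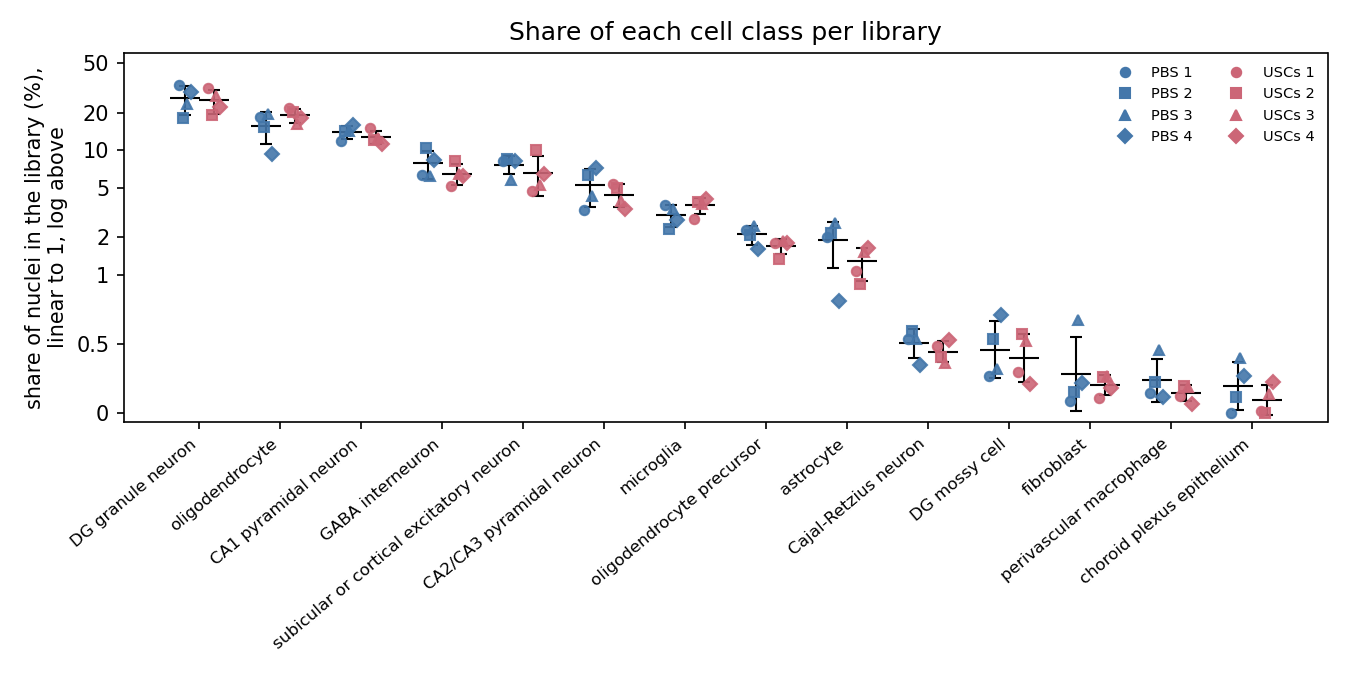
Share of nuclei in each cell class (percent of the nuclei of the library, axis linear to 1 and log above), each library a point, with the mean and SD of 4 libraries as black bars. The PBS and USCs libraries overlapped in every class.

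Genes differed between the groups in most large classes. The number called at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 708 in DG granule neurons, 498 in CA1, 355 in CA2/CA3, 239 in oligodendrocytes, 187 in microglia, 126 in GABA interneurons and 59 in subicular or cortical excitatory neurons. Of all calls, those over all nuclei (579) included, 2751 of 2751 kept their direction with DESeq2, which the use of the same counts made nearly certain. PBS 4 stood apart from the other PBS libraries. On a scale where 0 is the mean of the other PBS libraries and 1 that of the USCs libraries, its median position over 500 genes chosen without it lay between 0.713 and 0.878 in 7 sets of nuclei. PBS 1 to 3, held out in the same way, reached 0.527 at most, and the lowest USCs library lay at 0.847. Of 192 named genes called, 54, 23, 108 and 192 were still called without PBS 1, 2, 3 and 4, and 33, 1, 2 and 1 without USCs 1, 2, 3 and 4, while 192 of 192 kept their direction in each of these. Most calls had no overlap between the groups, 686 of 708 in DG granule neurons. Such a gene can hardly reverse with 1 library left out, so the kept directions are no support.

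**Figure D2:**
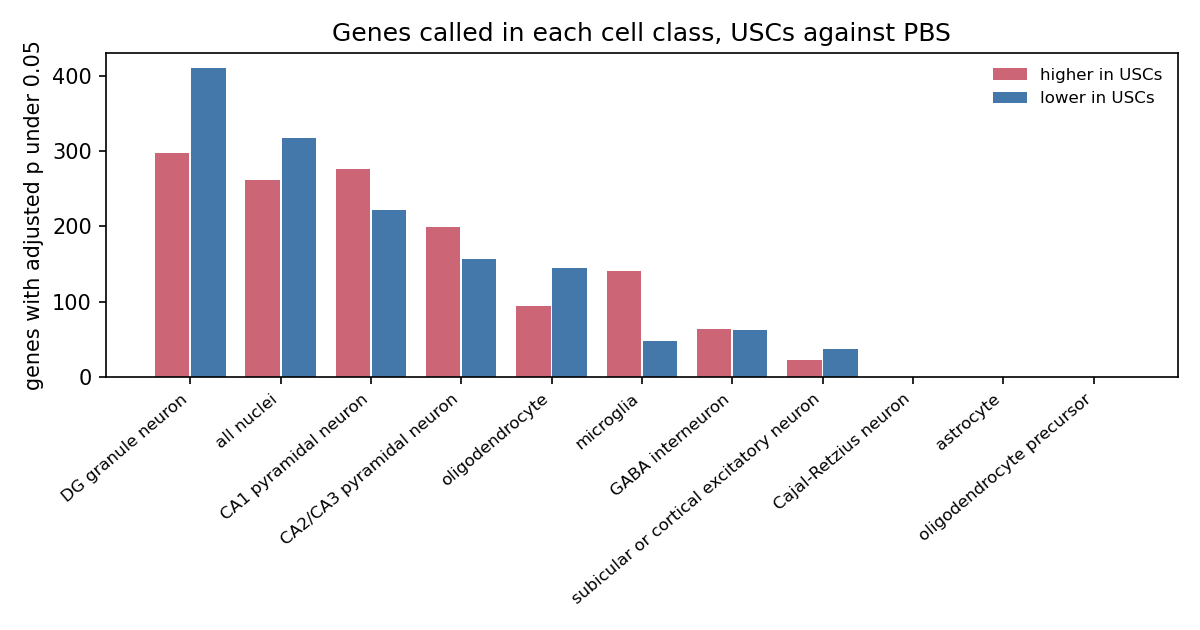
Number of genes called higher or lower in USCs than in PBS libraries in each cell class (adjusted p under 0.05, edgeR). DG granule neurons had most calls, 298 higher and 410 lower, and 3 classes had 0.

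**Figure D3:**
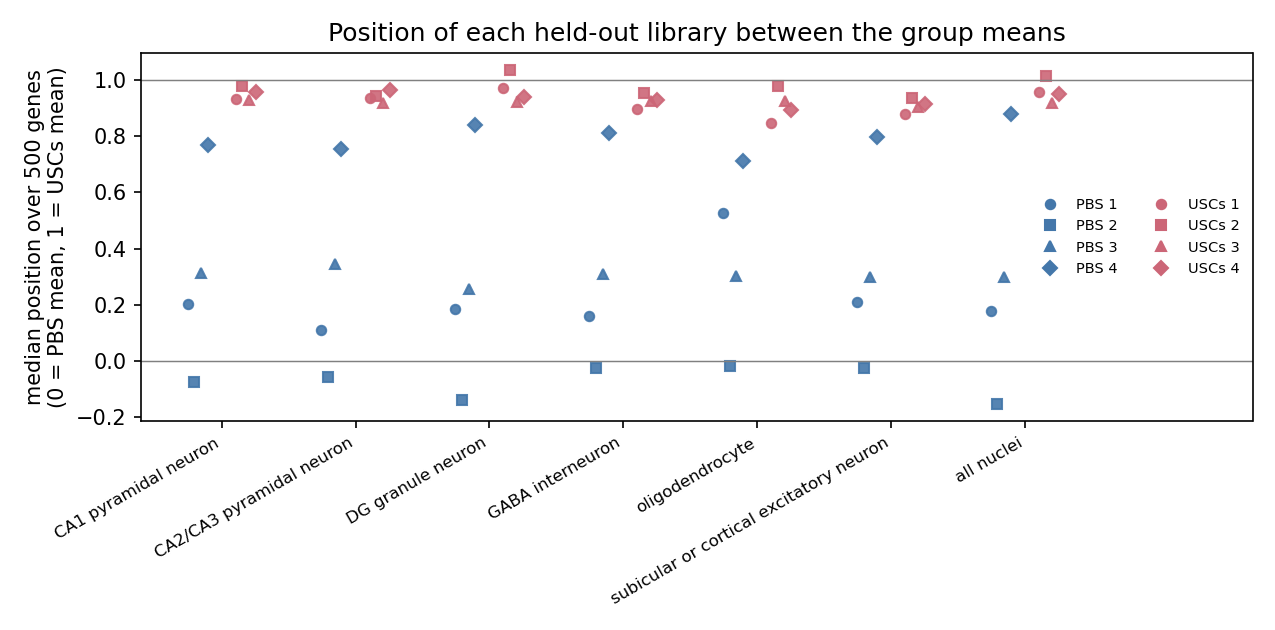
Median position of each library over 500 genes chosen without it, on a scale from the mean of the PBS libraries (0) to that of the USCs libraries (1), for 7 sets of nuclei. PBS 4 lay between 0.713 and 0.878, above the other PBS libraries and below the USCs libraries in each set.

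In DG granule neurons, genes called higher in USCs libraries included Pdia4, Xbp1, Arc and Egr1, and those called lower Mt1 and Sdha. Pdia4, a protein disulfide isomerase of the endoplasmic reticulum (ENSMUSG00000025823, GRCm38 chromosome 6, 47796141 to 47813430), rose from 6.42 ± 2.81 to 15.3 ± 1.43 CPM (2.34-fold, log2 1.23 ± 0.25 SE). Xbp1, a transcription factor of the unfolded protein response (ENSMUSG00000020484, chromosome 11, 5520659 to 5525893), rose from 11.7 ± 1.84 to 17.3 ± 0.922 CPM (1.48-fold). Arc, an immediate early gene of synaptic plasticity (ENSMUSG00000022602, chromosome 15, 74669083 to 74672570), rose from 1.29 ± 0.185 to 3.27 ± 0.158 CPM (2.49-fold), and Egr1, an immediate early transcription factor, from 1.44 ± 0.526 to 3.50 ± 0.606 CPM (2.42-fold). Ctnna3, an alpha-catenin of cell junctions (ENSMUSG00000060843, chromosome 10, 63430098 to 65003667), rose from 141 ± 11.3 to 344 ± 35.3 CPM (2.43-fold, log2 1.28 ± 0.10 SE).

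Further rises in DG granule neurons were those of Doc2b, a calcium sensor of vesicle release (26.2 ± 6.45 to 60.6 ± 4.47 CPM), Rph3al, a Rab effector in exocytosis (11.8 ± 3.02 to 33.1 ± 3.32 CPM), and Sema3e, a secreted guidance cue (6.50 ± 2.08 to 14.4 ± 2.90 CPM). Shank2, a scaffold of the postsynaptic density, rose 1.39-fold, and the potassium channel genes Kcnc1 and Kcnq5 1.45-fold and 1.66-fold. Hlf and Nfil3, transcription factors tied to the circadian clock, rose 1.41-fold and 1.64-fold. Bin1, an adaptor of membrane bending, rose 1.28-fold, and Sirt2, a deacetylase, 1.30-fold. The falls were led by Zfp46, a zinc finger gene (80.0 ± 34.9 to 23.6 ± 1.67 CPM, 3.39-fold), in which PBS 4 had 29.6 CPM. Mt1, a metal-binding metallothionein (ENSMUSG00000031765, chromosome 8, 94179082 to 94180327), fell from 14.1 ± 4.32 to 6.47 ± 0.403 CPM (2.16-fold), and Tdo2, which breaks down tryptophan, from 14.6 ± 2.63 to 7.17 ± 0.868 CPM. Tdo2 marked only cluster 1 of DG granule clusters 1, 4 and 7. Cluster 1 held 9.03% of PBS (14.9% of PBS 4) and 4.86% of USCs nuclei. Shifts between these clusters were not parted from expression. Abca1, a cholesterol exporter, and Ctso, a cathepsin, fell 2.11-fold and 2.67-fold. Sdha, a subunit of succinate dehydrogenase, fell from 83.4 ± 1.12 to 65.1 ± 3.77 CPM and Prdx1, a peroxiredoxin, from 13.01 ± 1.86 to 7.90 ± 0.283 CPM. Bdnf, a neurotrophin, was at 72.2 ± 22.6 and 67.6 ± 7.30 CPM and did not pass the threshold (adjusted p = 0.805 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Fos was too low to test, at 0.240 ± 0.230 and 0.988 ± 0.262 CPM.

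**Figure D4:**
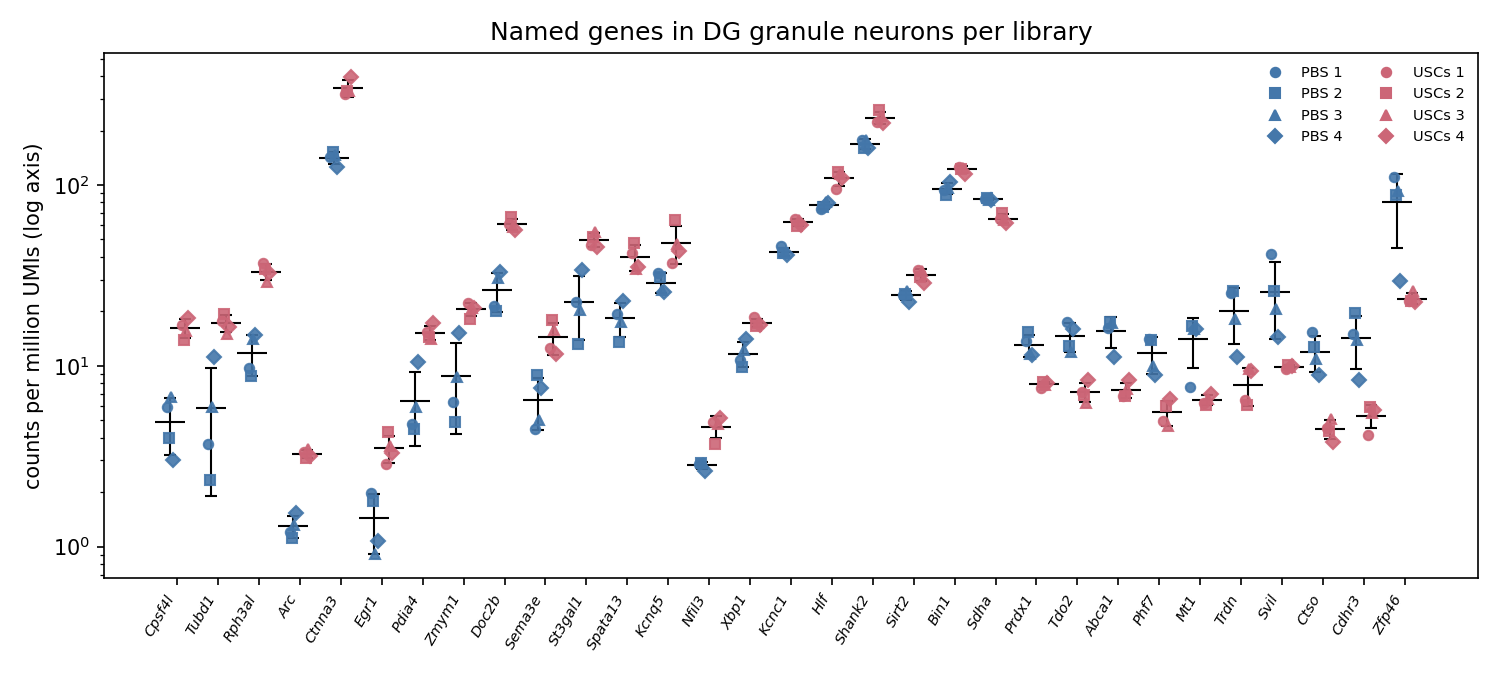
CPM (log axis) of genes called in DG granule neurons, each library a point, with the mean and SD of 4 libraries per group as black bars. For Arc the USCs libraries, at 3.27 ± 0.158, lay above all PBS libraries, at 1.29 ± 0.185.

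Of the 6 lists called in DG granule neurons, that of the unfolded protein and integrated stress response rose, with 2 of 17 measured members past the threshold over all genes tested and 2 adjusted over the list alone (median log2 change 0.38). Immediate early genes rose with 2 of 21 members past it and 4 adjusted over the list alone. Myelin genes, made by oligodendrocytes, rose in droplets of these neurons with 0 of 17 members past it and 2 adjusted over the list alone (median 0.64), and so did homeostatic microglia genes with 0 of 11 and 0. RNA set free during preparation can enter any droplet, and its upper bound, known only for microglia, was 6.36% to 11.6% of microglial UMIs in USCs libraries and 1.14% to 6.14% in PBS libraries. Summed CPM of the myelin genes, as a percent of their CPM over all nuclei, was 24.9% ± 3.29 in PBS and 27.6% ± 3.36 in USCs libraries, and that of the homeostatic microglia genes 114% ± 11.6 in PBS and 116% ± 10.4 in USCs libraries. Both lists scored lowest in PBS 4 (-1.21 and -0.67), and free RNA was not parted from expression in these neurons. Cytosolic ribosomal proteins fell with 0 of 42 and 0 (median -0.42), and nuclear-encoded oxidative phosphorylation genes with 1 of 35, Sdha, and 1 (median -0.25). All 6 list calls were lost, each at adjusted p = 0.888 with an estimated correlation. The homeostatic microglia genes list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 4 (0.0582). Myelin genes (median 0.64 to 0.35) and immediate early genes were not called by camera (Benjamini-Hochberg adjusted p) without PBS 4 (0.0529 each). Camera (Benjamini-Hochberg adjusted p) called neither oxidative phosphorylation (0.727, median -0.25 to -0.01) nor ribosomal proteins (0.833, median -0.42 to -0.02) without PBS 4. The unfolded protein response list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 3 (0.0572). In DG granule neurons without PBS 4, members past the threshold by edgeR in the direction of their list numbered 3 for homeostatic microglia genes, 3 for myelin genes, 6 for immediate early genes, 4 for oxidative phosphorylation, 1 for ribosomal proteins and 9 for the unfolded protein response. Without PBS 1, they numbered 1 for immediate early genes, 0 for oxidative phosphorylation and 0 for the unfolded protein response. Without PBS 3, they numbered 1 for immediate early genes and 0 for the unfolded protein response. Without PBS 2, USCs 1, USCs 2, USCs 3 or USCs 4, they numbered 0 for every list named here. Without PBS 4, 1 list was called, that of the unfolded protein response, whose median was 0.67 there and 0.23 without PBS 1. The median of myelin genes was 1.07 without PBS 3.

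The 708 DG calls comprised 298 rises and 410 falls among 15125 genes tested, and the named ones had adjusted p from 0.00315 to 0.0478 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In 16.5% of all genes tested every USCs library lay on 1 side of every PBS library, against 2.86% by chance. Genes of a library vary together, so here and in the sets below a higher share is no test against chance. The count was 1468 with DESeq2. It was 43 without PBS 1, 52 without PBS 2, 4296 without PBS 4, and 1, 1, 2 and 1 without USCs 1, 2, 3 and 4. Ctnna3, Doc2b, Rph3al, Sema3e, Shank2, Kcnq5, Bin1, Sirt2, Sdha and Bdnf overlap an annotated gene on the other strand and are uncertain in this respect.

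In CA1 pyramidal neurons, Arc rose from 14.3 ± 3.84 to 32.4 ± 6.12 CPM (2.25-fold) and Fosl2, a subunit of the AP-1 transcription factor, from 5.38 ± 1.50 to 13.1 ± 1.10 CPM (2.41-fold). Dlg4, which encodes the postsynaptic scaffold PSD-95 (ENSMUSG00000020886, chromosome 11, 70016942 to 70047522), rose from 77.8 ± 6.19 to 126 ± 4.19 CPM (1.62-fold, log2 0.70 ± 0.09 SE). Pdia4 rose from 4.37 ± 1.51 to 10.1 ± 1.23 CPM and Xbp1 from 11.7 ± 0.546 to 17.7 ± 1.77 CPM. Sdha fell from 86.2 ± 2.04 to 66.7 ± 1.66 CPM.

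The largest rises in CA1 were those of Spink13, a serine protease inhibitor gene (2.88 ± 1.80 to 13.8 ± 1.89 CPM, 4.64-fold), and Shoc1, a meiosis gene (12.97 ± 7.15 to 52.0 ± 11.3 CPM). Nfe2l2, which encodes the antioxidant regulator Nrf2, rose 2.75-fold from 1.09 ± 0.210 CPM, and Irf9, of interferon signalling, 2.52-fold. Unc13a, which primes synaptic vesicles, rose 1.45-fold, Atg7, of autophagy, 1.36-fold, Nfil3 2.63-fold, and Zbtb16, a glucocorticoid-responsive transcription factor, 1.45-fold. Tapbp, of antigen loading, rose 1.92-fold. Falls included Ciart, a repressor of the clock (10.0 ± 1.79 to 4.61 ± 0.835 CPM), Acat2, of sterol synthesis (2.01-fold), and Ntsr2, a neurotensin receptor (2.29-fold). Bdnf (34.6 ± 12.01 and 44.7 ± 3.96 CPM) and Grin2a, an NMDA receptor subunit (4043 ± 408 and 4614 ± 334 CPM), did not pass the threshold, with adjusted p of 0.359 and 0.370 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

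In CA1, 6 lists were called. Immediate early genes rose with 2 of 23 members past the threshold over all genes tested and 9 adjusted over the list alone, and neurotrophic and growth factor genes with 0 of 18 and 2. The unfolded protein response list rose with 2 of 17 and 2. Myelin genes rose in droplets of CA1 neurons with 1 of 15, Aspa, an enzyme of oligodendrocytes at 0.308 ± 0.181 and 1.21 ± 0.0643 CPM, and 4 adjusted over the list alone. Summed CPM of these myelin genes was 17.5% ± 2.56 in PBS and 19.6% ± 2.48 in USCs libraries of that over all nuclei. Free RNA was not parted from expression in CA1. Ribosomal proteins fell with 0 of 42 and 0, and oxidative phosphorylation genes with 1 of 35 and 2. The 6 calls were lost, at adjusted p = 0.560 with an estimated correlation for the immediate early and growth factor lists, adjusted p = 0.764 with an estimated correlation for myelin and adjusted p = 0.940 with an estimated correlation for the others. Camera (Benjamini-Hochberg adjusted p) called neither oxidative phosphorylation (0.873, median -0.17 to -0.03) nor ribosomal proteins (0.418, median -0.36 to 0.11) without PBS 4. The unfolded protein response list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 1 (0.0656), PBS 2 (0.194), PBS 3 (0.117) and USCs 1 (0.108). The growth factor signalling list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 3 (0.0572). In CA1 without PBS 4, members past the threshold by edgeR in the direction of their list numbered 5 for myelin genes, 10 for immediate early genes, 3 for oxidative phosphorylation, 7 for the unfolded protein response and 6 for growth factor signalling. In CA1 without PBS 1 or PBS 2, they numbered 0 for myelin genes, 1 for immediate early genes, 0 for oxidative phosphorylation and 0 for the unfolded protein response. In CA1 without PBS 3, they numbered 1 for growth factor signalling. In CA1 without USCs 1, USCs 2, USCs 3 or USCs 4, they numbered 0 for every list named here.

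CA1 had 276 rises and 222 falls among 14608 genes, with adjusted p of the named calls from 0.0155 to 0.0494 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the count was 1106 with DESeq2. It was 38 without PBS 1, 23 without PBS 2, 3165 without PBS 4, and by edgeR 0 without USCs 1, 2, 3 or 4, where 2615, 2500, 2387 and 2474 genes had an unadjusted p under 0.05 and DESeq2 was not run. Groups did not overlap in 14.9% of all genes tested, against 2.86% by chance. Spink13, Shoc1, Unc13a, Tapbp, Ciart, Sdha and Bdnf overlap an annotated gene on the other strand.

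The CA2/CA3 class was cluster 26. Its markers Rgs14, Amigo2 and Cacng5 marked unnamed cluster 29 instead, so CA2 may be missing from the class. In CA2/CA3 pyramidal neurons, Pdia4 rose from 4.56 ± 1.79 to 12.4 ± 1.16 CPM (2.59-fold) and Xbp1 from 9.97 ± 2.29 to 19.9 ± 2.44 CPM (1.96-fold). Gria2, an AMPA receptor subunit, fell from 3621 ± 226 to 2572 ± 72.8 CPM (1.41-fold), Gphn, the gephyrin scaffold of inhibitory synapses, from 1020 ± 143 to 723 ± 34.7 CPM, and the sodium channel genes Scn2a and Scn1a 1.42-fold and 1.36-fold. Dlg4 rose from 51.6 ± 9.88 to 81.9 ± 6.69 CPM and Kcnc1 1.39-fold. Sdha fell from 84.1 ± 4.24 to 60.4 ± 2.31 CPM, and Mt2, a metallothionein, from 3.88 ± 0.716 to 1.06 ± 0.363 CPM (3.52-fold).

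Other CA2/CA3 rises were those of Spink13 (4.64 ± 4.13 to 28.9 ± 3.81 CPM, 5.56-fold), Nfe2l2 (0.975 ± 0.752 to 4.95 ± 1.95 CPM), Cbfa2t3, a transcriptional corepressor (6.16 ± 2.78 to 20.9 ± 2.94 CPM), Tnfrsf25, a death receptor (3.24-fold), and Pfkfb3, a regulator of glycolysis (1.39-fold). Falls included Zfp46 (3.41-fold), Fbn1, fibrillin-1 (2.41-fold), Yes1, a Src-family kinase (2.30-fold), Lama2, a laminin chain (1.96-fold), Dbp, a clock output factor (2.03-fold), and H2-D1, an MHC class I gene with close paralogs and so uncertain (2.01-fold). The list of the unfolded protein response rose with 2 of 16 members past the threshold over all genes tested and 5 adjusted over the list alone, immediate early genes with 0 of 17 and 0, and myelin genes with 0 of 10 and 0. Summed CPM of the myelin genes in CA2/CA3 was 15.4% ± 3.36 in PBS and 16.5% ± 1.72 in USCs libraries of that over all nuclei, and free RNA was not parted from expression. Ribosomal proteins fell with 0 of 42 and 0 and oxidative phosphorylation genes with 1 of 35 and 1. Each of these 5 lists had adjusted p = 0.964 with an estimated correlation, and the number called was 1 without PBS 4 and 3 without USCs 3. The myelin genes list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 4 (0.638, median 0.41 to 0.17), USCs 3 (0.0678, median 0.41 to 0.27) and USCs 4 (0.0569). The immediate early genes list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 4 (0.0510), USCs 1 (0.172) and USCs 3 (0.189). Camera (Benjamini-Hochberg adjusted p) called neither oxidative phosphorylation (0.447, median -0.26 to -0.08) nor ribosomal proteins (0.926, median -0.43 to 0.06) without PBS 4. In CA2/CA3 without PBS 4, members past the threshold by edgeR in the direction of their list numbered 1 for myelin genes, 7 for immediate early genes, 2 for oxidative phosphorylation and 9 for the unfolded protein response. In CA2/CA3 without PBS 1, PBS 2, USCs 1, USCs 2, USCs 3 or USCs 4, they numbered 0 for every list named here. CA2/CA3 had 199 rises and 156 falls among 12855 genes, the named ones at adjusted p from 0.0130 to 0.0494 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 628 calls with DESeq2. By edgeR the count was 2472 without PBS 4, 0 without PBS 1 or PBS 2 and 0, 0, 1 and 0 without USCs 1, 2, 3 and 4. For these 6, 2280, 2352, 2167, 2134, 2060 and 2088 genes had an unadjusted p under 0.05, and DESeq2 was not run. Spink13, Cbfa2t3, Fbn1, Gphn, Scn1a, Sdha, Mt2, Pfkfb3, Yes1, Lama2 and Dbp overlap an annotated gene on the other strand.

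GABA interneurons shared the rises of Xbp1 (9.86 ± 1.85 to 18.4 ± 1.63 CPM, 1.85-fold), Dlg4 (35.6 ± 4.16 to 54.0 ± 3.54 CPM) and Unc13a (86.1 ± 12.1 to 130 ± 13.5 CPM). Nr4a3, an immediate early nuclear receptor, rose from 3.52 ± 1.49 to 10.6 ± 1.56 CPM (3.01-fold), and Tubb3, a neuronal tubulin, 1.43-fold. Alkal2, which encodes a ligand of the ALK receptor, rose too (21.0 ± 3.39 to 55.5 ± 6.67 CPM, 2.64-fold, log2 1.40 ± 0.14 SE). Ptbp2, a regulator of neuronal splicing, fell from 209 ± 19.6 to 113 ± 4.40 CPM (1.85-fold), Mrpl41, a mitochondrial ribosomal protein, from 56.1 ± 6.78 to 30.2 ± 3.94 CPM, and Rad18, of DNA repair, 2.51-fold. The lists of immediate early genes (1 of 17 members past the threshold over all genes tested, 1 adjusted over the list alone) and of the unfolded protein response (1 of 16, and 2) rose, both at adjusted p = 0.761 with an estimated correlation. The number of lists called was 4 without PBS 3 or PBS 4, and 0 of 32 without USCs 2 by camera. The immediate early genes list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 4 (0.217, median 0.25 to 0.08) and USCs 2 (0.0546). The unfolded protein response list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 1 (0.0561, median 0.44 to 0.27), PBS 2 (0.0837) and USCs 2 (0.0530). In interneurons without PBS 4, members past the threshold by edgeR in the direction of their list numbered 3 for immediate early genes and 8 for the unfolded protein response. In interneurons without PBS 1, PBS 2, PBS 3, USCs 1, USCs 2, USCs 3 or USCs 4, they numbered 0 for every list named here.

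Interneurons had 64 rises and 62 falls among 13504 genes, with adjusted p of the named genes from 0.00573 to 0.0476 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 345 calls with DESeq2. The count was 3 without PBS 1, 3 without PBS 2, 64 without PBS 3, 2003 without PBS 4, and by edgeR 0, 0, 1 and 0 without USCs 1, 2, 3 and 4, where 2025, 1860, 1864 and 1826 genes had an unadjusted p under 0.05 and DESeq2 was not run. Alkal2, Unc13a and Ptbp2 overlap an annotated gene on the other strand.

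In subicular or cortical excitatory neurons, Shank2 rose from 158 ± 10.3 to 231 ± 19.6 CPM (1.46-fold) and Cacng8, an auxiliary subunit of AMPA receptors, from 35.4 ± 7.57 to 71.2 ± 10.4 CPM (2.02-fold). Bicd2, a dynein adaptor, rose 2.02-fold. Cirbp, a cold-inducible RNA-binding protein, fell from 24.3 ± 2.13 to 11.3 ± 1.60 CPM (2.14-fold), Ptbp2 from 234 ± 40.0 to 129 ± 9.57 CPM, and Stmn1, a regulator of microtubules, from 83.6 ± 11.7 to 50.8 ± 3.75 CPM. Lists that rose were immediate early genes (0 of 21 members past the threshold over all genes tested, 2 adjusted over the list alone), the unfolded protein response (0 of 15, and 2) and myelin genes (0 of 16, and 0), and those that fell were oxidative phosphorylation (0 of 35, and 0) and ribosomal proteins (0 of 42, and 0). Summed CPM of the myelin genes in subicular or cortical neurons was 35.7% ± 17.5 in PBS and 32.5% ± 3.22 in USCs libraries of that over all nuclei, and free RNA was not parted from expression. The lists had adjusted p = 0.746 with an estimated correlation, and the ribosomal list adjusted p = 0.793 with an estimated correlation. The number of lists called was 8 without PBS 1, 11 without USCs 1 and 9 without USCs 4. The myelin genes list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 4 (0.0739, median 0.32 to 0.07). The oxidative phosphorylation list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 4 (0.496, median -0.23 to -0.07). The ribosomal proteins list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 4 (0.917, median -0.31 to -0.03). The unfolded protein response list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 2 (0.101, median 0.35 to 0.21). In subicular or cortical neurons without PBS 4, members past the threshold by edgeR in the direction of their list numbered 2 for myelin genes, 3 for immediate early genes, 2 for oxidative phosphorylation and 5 for the unfolded protein response. There were 22 rises and 37 falls among 13294 genes, the named ones at adjusted p from 0.0173 to 0.0432 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 306 calls with DESeq2, 166 of them rises. By edgeR the count was 1695 without PBS 4, 0 without PBS 1 or PBS 2 and 0, 1, 0 and 0 without USCs 1, 2, 3 and 4. For these 6, 1840, 1813, 1933, 1757, 1770 and 1798 genes had an unadjusted p under 0.05, and DESeq2 was not run. Shank2, Cacng8 and Ptbp2 overlap an annotated gene on the other strand.

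In microglia of the USCs libraries, Apoe, Arhgap24, Mt1 and H2-K1 were lower, and genes known from neurons higher. Apoe, an apolipoprotein of lipid transport raised in disease-associated microglia (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), fell from 558 ± 314 to 183 ± 38.6 CPM (3.05-fold, log2 -1.61 ± 0.32 SE), with 984 CPM in PBS 4. Arhgap24, a gene on the same list, fell from 391 ± 47.5 to 200 ± 41.6 CPM (1.96-fold), Mt1 from 46.9 ± 15.0 to 13.1 ± 4.74 CPM (3.58-fold), and H2-K1, an MHC class I gene with close paralogs and so uncertain, from 117 ± 15.3 to 58.3 ± 20.9 CPM. Zc3h6, a zinc finger gene, fell 3.85-fold, Las1l, of ribosome assembly, 2.97-fold, and Slco4a1, an organic anion transporter, 2.91-fold. C1qa, a complement gene, was at 663 ± 592 and 370 ± 43.3 CPM and did not pass the threshold (adjusted p = 0.295 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with 1550 CPM in PBS 4. Cst7 had 0 to 2 UMIs per library and was not tested.

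The microglial rises included Grin2a (147 ± 48.3 to 345 ± 66.8 CPM, 2.33-fold), the presynaptic adhesion gene Nrxn3 (309 ± 106 to 669 ± 196 CPM), the GABA receptor gene Gabra2 (56.6 ± 11.9 to 140 ± 36.9 CPM), the potassium channel gene Kcnd2 (218 ± 117 to 496 ± 74.1 CPM), the guidance receptor gene Epha6 (139 ± 48.9 to 329 ± 98.1 CPM) and Nrg3, a neuregulin (346 ± 138 to 794 ± 259 CPM). Sh3rf1, a scaffold of JNK signalling, rose from 7.79 ± 1.14 to 38.1 ± 3.81 CPM (4.78-fold), and Chrm3, a muscarinic receptor, 3.79-fold. Lists of such genes rose: glutamate receptors and postsynaptic density (7 of 20 members past the threshold over all genes tested, 15 adjusted over the list alone), GABA synapse (3 of 15, and 7), presynaptic vesicle machinery (4 of 15, and 9), voltage-gated channels (5 of 19, and 14), axon guidance and adhesion (7 of 19, and 15) and neurotrophic and growth factor signalling (2 of 8, and 6, with 1 fall). Myelin genes (0 of 6, and 2) and heat shock chaperones (0 of 9, and 2) rose as well. These 8 list calls were lost, at adjusted p = 0.390 to adjusted p = 0.485 with an estimated correlation. The myelin genes list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 1 (0.0874), PBS 4 (0.135, median 0.93 to 0.58), USCs 1 (0.0746), USCs 2 (0.0564), USCs 3 (0.141) and USCs 4 (0.0637). In microglia without PBS 1, members past the threshold by edgeR in the direction of their list numbered 5 for the GABA synapse and 5 for growth factor signalling. Without PBS 2, they numbered 4 for glutamate receptors, 1 for the GABA synapse, 1 for presynaptic vesicle machinery, 0 for voltage-gated channels, 0 for axon guidance and 0 for growth factor signalling. Without PBS 4, they numbered 1 for myelin genes, 1 for heat shock chaperones and 4 for growth factor signalling. Against that direction passed 1 member of growth factor signalling and 1 of voltage-gated channels, of which 6 rose there. In microglia without PBS 3, they numbered 3 for glutamate receptors, 1 for the GABA synapse, 0 for presynaptic vesicle machinery, 0 for voltage-gated channels, 0 for axon guidance and 0 for growth factor signalling. Without USCs 1, they numbered 3 for voltage-gated channels. Without USCs 2, USCs 3 or USCs 4, they numbered 0 for every list named here. RNA of neurons set free during preparation can enter any droplet, and its upper bound was 4.21% ± 2.17 of microglial UMIs in PBS and 9.40% ± 2.32 in USCs libraries, with 1.14% in PBS 4.

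Lists that fell in microglia were disease-associated microglia genes (2 of 10 members past the threshold over all genes tested, 4 adjusted over the list alone), complement (0 of 8, and 1), ribosomal proteins (0 of 39, and 0), mitochondrially encoded transcripts (0 of 8, and 0) and lysosome and autophagy (0 of 19, and 0). These 5 list calls were lost as well, at adjusted p = 0.390 to adjusted p = 0.485 with an estimated correlation. The complement list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 4 (0.515, median -0.68 to -0.24), USCs 1 (0.0529) and USCs 2 (0.0835). The mitochondrially encoded transcripts list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 3 (0.0725, median -0.52 to -0.30). The lysosome and autophagy list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 4 (0.135). The median of disease-associated microglia genes was -0.54, and -0.30 without PBS 4. For these lists without PBS 1, members past the threshold by edgeR in the direction of their list numbered 1 for complement and 2 for ribosomal proteins. Without PBS 3, they numbered 1 for disease-associated microglia genes. Without PBS 4, they numbered 1 for ribosomal proteins. Without USCs 2, USCs 3 or USCs 4, they numbered 0 for every list named here. Homeostatic microglia genes were not called (adjusted p = 0.759 by camera with Benjamini-Hochberg adjustment). Microglia had 140 rises and 47 falls among 6900 genes, with adjusted p of the named genes from 0.0124 to 0.0498 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 194 calls with DESeq2. Groups did not overlap in 10.1% of all genes tested, against 2.86% by chance. The count was 56 without PBS 2, 60 without PBS 3, 445 without PBS 4, and 1, 1 and 1 without USCs 2, 3 and 4. When the microglial cluster with many nuclei marked as doublets was kept, an alternative chosen after the data had been seen, edgeR called 0 genes, with 356 at an unadjusted p under 0.05, and camera 5 lists. Of 33 named genes called, 14 kept their direction there and the others reversed, among them Grin2a, Nrxn3, Kcnd2, Epha6, Nrg3, Sh3rf1 and Chrm3. Arhgap24, Nrxn3, Epha6, Nrg3, Sh3rf1, Chrm3 and Zc3h6 overlap an annotated gene on the other strand.

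**Figure D5:**
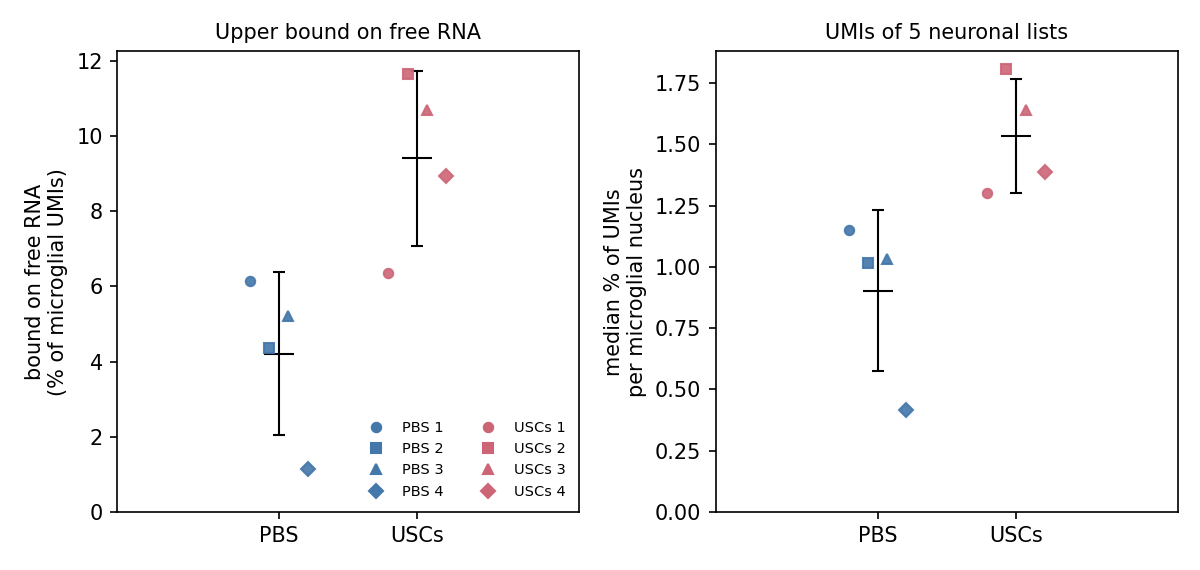
Left, upper bound on free RNA as percent of microglial UMIs; right, median percent of UMIs per microglial nucleus from 5 lists of synaptic, channel and guidance genes; each point is a library and black bars give mean and SD of 4. The bound was 4.21% ± 2.17 in PBS and 9.40% ± 2.32 in USCs libraries, and the 5 lists took 0.903% ± 0.330 and 1.54% ± 0.233.

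In oligodendrocytes of the USCs libraries, Hspa4l, Hsph1 and Chordc1, chaperones and co-chaperones of the heat shock system, rose from 38.2 ± 8.99 to 74.1 ± 8.83, from 34.9 ± 9.26 to 69.2 ± 11.9 and from 57.6 ± 11.8 to 99.6 ± 10.3 CPM (1.97-fold, 2.02-fold and 1.75-fold). Tsc22d3, a glucocorticoid-induced leucine zipper, rose from 116 ± 45.2 to 218 ± 7.57 CPM (1.90-fold). Mt1 fell from 59.8 ± 18.1 to 28.6 ± 4.49 CPM (2.06-fold), Mt2 3.20-fold, and Per3, a clock gene, from 32.6 ± 7.26 to 17.3 ± 3.15 CPM. Fanca, a DNA repair gene (36.0 ± 23.5 to 5.88 ± 1.02 CPM, 6.29-fold), and Ddc, dopa decarboxylase (273 ± 199 to 69.0 ± 12.4 CPM), had 7.66 and 101 CPM in PBS 4. These values mix clusters 8 (most nuclei of PBS 1), 33 (PBS 2 and PBS 3) and 14 (PBS 4 and the USCs libraries). At resolution 2, PBS 4 gave 1018 of the 1117 nuclei of cluster 37, and the USCs oligodendrocytes lay mostly in clusters 13 and 45, with 38 and 26 nuclei of PBS 4.

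Bfsp2, a filament protein gene, rose in oligodendrocytes of these clusters 8, 33 and 14 from 30.0 ± 16.5 to 93.2 ± 5.99 CPM (3.16-fold), Kcnc2 2.39-fold and Gabra2 2.29-fold. Mbp, of myelin, was at 3722 ± 521 and 3384 ± 76.9 CPM, Il33, a cytokine, at 435 ± 124 and 522 ± 26.7 CPM, and C4b, a complement gene, at 241 ± 202 and 156 ± 75.5 CPM, with adjusted p of 0.659, 0.465 and 0.531 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The list of heat shock chaperones rose with 3 of 17 members past the threshold over all genes tested and 8 adjusted over the list alone, and the unfolded protein response with 0 of 14 and 0. Lists of neuronal genes rose in droplets of oligodendrocytes, as in microglia: glutamate receptors and postsynaptic density (0 of 24, and 0 adjusted over the list alone), GABA synapse (1 of 20, and 2), presynaptic vesicle machinery (0 of 22, and 0), voltage-gated channels (1 of 23, and 5, with 1 fall), axon guidance and adhesion (0 of 23, and 6) and growth factor signalling (0 of 15, and 3), as did homeostatic microglia genes (0 of 9, and 0). Summed CPM of the glutamate receptors and postsynaptic density list was 21.5% ± 2.83 in PBS and 26.4% ± 2.24 in USCs libraries of that over all nuclei, and that of presynaptic vesicle machinery 12.4% ± 4.29 in PBS and 18.2% ± 2.71 in USCs libraries. It was 45.9% ± 7.55 in PBS and 49.3% ± 2.60 in USCs libraries for the GABA synapse, 25.2% ± 5.55 in PBS and 26.6% ± 1.93 in USCs libraries for voltage-gated channels and 42.7% ± 2.38 in PBS and 49.1% ± 1.50 in USCs libraries for axon guidance. These 5 lists scored lowest in PBS 4 (-1.09 for glutamate receptors), which had the lowest bound on free RNA in microglia (1.14% of UMIs), and free RNA was not parted from expression in oligodendrocytes. Ribosomal proteins (0 of 42, and 0), oxidative phosphorylation (0 of 35, and 0), mitochondrially encoded transcripts (0 of 10, and 0) and cholesterol biosynthesis (0 of 18, and 0) fell. The 13 list calls were lost at adjusted p = 0.533 to adjusted p = 0.609 with an estimated correlation, and 7 were called without PBS 4. The homeostatic microglia genes list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 2 (0.113), PBS 4 (0.2003), USCs 3 (0.0760) and USCs 4 (0.0507). The GABA synapse list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 4 (0.111, median 0.34 to 0.15). The voltage-gated channels list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 4 (0.116, median 0.41 to 0.25). The mitochondrially encoded transcripts list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 3 (0.325, median -0.46 to -0.15), PBS 4 (0.110), USCs 1 (0.433, median -0.46 to -0.16) and USCs 2 (0.0776). The cholesterol biosynthesis list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 1 (0.0848), PBS 4 (0.0627) and USCs 4 (0.0513). The growth factor signalling list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 4 (0.0627). In oligodendrocytes of clusters 8, 33 and 14 without PBS 4, members past the threshold by edgeR in the direction of their list numbered 3 for glutamate receptors, 3 for the GABA synapse, 3 for voltage-gated channels, 3 for axon guidance, 1 for oxidative phosphorylation, 1 for ribosomal proteins, 7 for heat shock chaperones, 4 for the unfolded protein response, 2 for cholesterol biosynthesis and 1 for growth factor signalling. Without PBS 4 members also passed against that direction, 3 for voltage-gated channels, 1 for the GABA synapse and 1 for growth factor signalling. Without PBS 1, members past the threshold in their list's direction numbered 1 for glutamate receptors, 2 for voltage-gated channels and 1 for axon guidance. Without USCs 1, they numbered 0 for the GABA synapse and 1 for heat shock chaperones. Without PBS 2, PBS 3, USCs 2, USCs 3 or USCs 4, they numbered 0 for every list named here. The 5 neuronal lists took a median of 2.10% ± 0.224 of UMIs per oligodendrocyte nucleus in PBS and 2.52% ± 0.219 in USCs libraries.

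Oligodendrocytes of clusters 8, 33 and 14 together had 94 rises and 145 falls among 11398 genes, the named ones at adjusted p from 0.0120 to 0.0462 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 497 calls with DESeq2. The count was 145 without PBS 1, 17 without PBS 2, 30 without PBS 3, 1187 without PBS 4, and by edgeR 73, 0, 0 and 7 without USCs 1, 2, 3 and 4, where 2064, 1766, 1754 and 1886 genes had an unadjusted p under 0.05 and DESeq2 was not run. It was 52 with counts thinned to equal depth. Chordc1, Fanca, Ddc, Bfsp2, Mbp and Mt2 overlap an annotated gene on the other strand.

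Astrocytes, oligodendrocyte precursors and Cajal-Retzius neurons had 0 genes called by edgeR's quasi-likelihood test, with 403, 689 and 98 genes at an unadjusted p under 0.05 and 0, 1 and 0 calls by DESeq2. In astrocytes, Gfap, an intermediate filament raised in reactive astrocytes, was at 83.2 ± 17.4 and 83.7 ± 40.3 CPM, C4b at 131 ± 101 and 92.0 ± 33.7 CPM, and Apoe at 1840 ± 1513 and 1032 ± 458 CPM, with 4066 CPM in PBS 4. The smallest p in astrocytes were those of Hist1h2be, a histone gene with close paralogs (14.3 ± 7.59 and 43.5 ± 2.58 CPM), Gm44151 and Fam163a (47.6 ± 6.15 and 140 ± 55.6 CPM), each with an adjusted p of 0.690 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In precursors, Ctso was at 49.2 ± 14.6 and 9.48 ± 4.55 CPM (adjusted p = 0.0666 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 16 genes were called without PBS 4 and 6 without PBS 2. In Cajal-Retzius neurons, Rsrp1 was at 653 ± 133 and 276 ± 93.9 CPM, Tmem167 at 167 ± 13.8 and 49.1 ± 29.3 CPM and Cdh9 at 89.8 ± 48.6 and 259 ± 120 CPM. Gfap, Gm44151, Tmem167 and Cdh9 overlap an annotated gene on the other strand.

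Lists were called in 2 of these classes although no member passed over all genes tested. In astrocytes, cholesterol biosynthesis fell (0 of 11 members past the threshold over all genes tested, 2 adjusted over the list alone), as did ribosomal proteins (0 of 23, and 0), oxidative phosphorylation (0 of 20, and 0), mitochondrially encoded transcripts (0 of 8, and 0) and the circadian clock (0 of 16, and 0), while glutamate receptors (0 of 25, and 0) and axon guidance (0 of 21, and 0) rose. These had adjusted p = 0.697 with an estimated correlation, and the number called was 4 without PBS 1, 2 without PBS 3, 2 without USCs 1 and 1 without USCs 2. The glutamate receptors list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 1 (0.649, median 0.37 to 0.20), PBS 3 (0.0912), USCs 1 (0.0902) and USCs 2 (0.993, median 0.37 to -0.01). The axon guidance list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 1 (0.389, median 0.44 to 0.24), PBS 3 (0.0723), USCs 1 (0.210) and USCs 2 (0.336, median 0.44 to 0.04). The oxidative phosphorylation list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 3 (0.0878), USCs 1 (0.0618) and USCs 2 (0.176). The mitochondrially encoded transcripts list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 3 (0.667, median -0.95 to -0.10), USCs 1 (0.245) and USCs 2 (0.107). The cholesterol biosynthesis list was not called by camera (Benjamini-Hochberg adjusted p) without USCs 2 (0.121). The circadian clock list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 1 (0.584, median -0.25 to -0.04), PBS 3 (0.232), USCs 1 (0.0618) and USCs 2 (0.289). In precursors, oligodendrocyte differentiation (0 of 14, and 4 adjusted over the list alone), axon guidance (0 of 23, and 0) and the unfolded protein response (0 of 9, and 0) rose, at adjusted p = 0.544, adjusted p = 0.544 and adjusted p = 0.312 with an estimated correlation, and 8 lists were called without PBS 2. The axon guidance list of precursors was not called by camera (Benjamini-Hochberg adjusted p) without PBS 3 (0.207, median 0.28 to 0.15). In precursors without PBS 4, members past the threshold by edgeR in the direction of their list numbered 1 for oligodendrocyte differentiation and 2 for the unfolded protein response. Cajal-Retzius neurons had 0 lists called by camera, 1 without PBS 2 and 2 without USCs 4.

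Over all nuclei, where shares of cells and their expression are mixed, Arc rose from 6.18 ± 1.17 to 13.5 ± 2.66 CPM (2.17-fold), Dlg4 from 62.0 ± 5.19 to 91.5 ± 3.35 CPM (1.47-fold), Xbp1 1.58-fold and Pdia4 2.23-fold. Cryab, a small heat shock protein, rose from 3.44 ± 0.776 to 7.72 ± 0.693 CPM (2.24-fold), Tsc22d3 from 6.88 ± 1.42 to 15.2 ± 0.971 CPM (2.21-fold), Gjc3, a connexin of oligodendrocytes, from 19.1 ± 5.83 to 47.6 ± 7.24 CPM, and Gpr34, a receptor of microglia, 1.62-fold. Sdha fell from 91.8 ± 2.38 to 69.5 ± 2.13 CPM (1.32-fold), Mt1 from 14.8 ± 3.01 to 7.91 ± 0.675 CPM and Acat2 1.74-fold. Cdkn1a, a cell cycle inhibitor used as a marker of senescence, was at 2.36 ± 1.76 and 1.60 ± 0.499 CPM (adjusted p = 0.588 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Lists that rose were immediate early genes (1 of 26 members past the threshold over all genes tested, 7 adjusted over the list alone), the unfolded protein response (2 of 20, and 2), myelin genes (0 of 19, and 5), homeostatic microglia genes (1 of 14, and 2) and oligodendrocyte differentiation (1 of 16, and 1), and those that fell were oxidative phosphorylation (1 of 35, and 1) and ribosomal proteins (0 of 42, and 0). Each of the 7 had adjusted p = 0.958 with an estimated correlation. The oligodendrocyte differentiation list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 2 (0.0695), PBS 4 (0.192, median 0.12 to 0.08) and USCs 2 (0.0711). The oxidative phosphorylation list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 4 (0.656, median -0.23 to -0.00363). The ribosomal proteins list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 4 (0.986, median -0.34 to 0.00202). The unfolded protein response list was not called by camera (Benjamini-Hochberg adjusted p) without PBS 1 (0.0780), PBS 2 (0.0829), PBS 3 (0.0936) and USCs 2 (0.0597). Over all nuclei without PBS 4, members past the threshold by edgeR in the direction of their list numbered 2 for homeostatic microglia genes, 6 for myelin genes, 2 for oligodendrocyte differentiation, 7 for immediate early genes, 4 for oxidative phosphorylation and 10 for the unfolded protein response. Without PBS 3, they numbered 0 for homeostatic microglia genes, 2 for oligodendrocyte differentiation and 2 for oxidative phosphorylation. Without PBS 1, PBS 2, USCs 1, USCs 2, USCs 3 or USCs 4, they numbered 0 for every list named here.

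Over all nuclei there were 262 rises and 317 falls among 19722 genes, the named ones at adjusted p from 0.0198 to 0.0492 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 2220 calls with DESeq2. By edgeR the count was 4748 without PBS 4 and 0 without PBS 1, PBS 2 or USCs 1, 2, 3 or 4, where 3682, 3603, 3672, 3537, 3394 and 3401 genes had an unadjusted p under 0.05 and DESeq2 was not run. Groups did not overlap in 16.3% of all genes tested, against 2.86% by chance. Cryab, Gpr34, Sdha and Cdkn1a overlap an annotated gene on the other strand.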

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

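The tests of opposite strands in PBS 4, of a shared preparation difference and of other splits of the libraries were chosen only after the results were seen. For the mislabelled library, the test was written before its value was seen.

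In 1 group of 4 libraries in about 20, chance alone sets 1 library this far from the others. Among measures of libraries, total UMIs of PBS 4 (102319067) were far above those of the other PBS libraries and the mitochondrial share of PBS 3 (0.121%) far above theirs, 2 of 22 groups. Among shares of classes, oligodendrocyte precursors in USCs 2 (1.34%) and subicular or cortical excitatory neurons in PBS 3 (5.80%) lay far below their groups, 2 of 28. Of 424 groups of named genes 25 had such a library, against 21.2 expected by chance, and in 13 of the 25 it was PBS 4.

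PBS 4 lay far from the other PBS libraries for Faap100 (7.73 CPM), Akr1b10 (7.65 CPM) and Grin2a (4649 CPM) in CA1, Xbp1 in CA2/CA3 (13.4 CPM), Cdh9 in Cajal-Retzius neurons (162 CPM), Nfil3 in DG granule neurons (2.62 CPM) and Dlg4 in GABA interneurons (29.5 CPM). It did so for Nrxn3 (152 CPM), Epha5 (29.8 CPM) and C1qa (1550 CPM) in microglia, Tsc22d3 in oligodendrocytes, where it lay in cluster 14 and the other PBS libraries in clusters 8 and 33 (183 CPM), and Lca5 (38.0 CPM) and Dlg4 (54.3 CPM) over all nuclei. Other libraries far from their group were USCs 4 for Pdia4 in CA1 (11.9 CPM), Zfp46 in CA2/CA3 (6.82 CPM) and Ctnna3 in DG granule neurons (396 CPM), and USCs 3 for Zfp46 in DG granule neurons (26.0 CPM), Rad18 (12.5 CPM) and Ptbp2 (106 CPM) in GABA interneurons and Iqck in subicular or cortical neurons (4.56 CPM). The rest were USCs 1 for Gria2 in CA2/CA3 (2681 CPM) and H2-K1 in microglia (89.4 CPM), USCs 2 for Scn1a (238 CPM) and PBS 3 for Gphn (808 CPM) in CA2/CA3, and PBS 1 for Mt1 in DG granule neurons (7.59 CPM). About 1 in 20 groups is expected to show this by chance.

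PBS 4 stood apart from PBS 1 to 3. A mislabelled USCs library is argued against as the whole cause, since in DG granule neurons the smallest chi-square per degree of freedom between PBS 4 and a USCs library (42.1) was 6.16 times the largest between USCs libraries. Its smallest distance to another PBS library was 57.4, against 18.6 at most between PBS 1 to 3, so these distances do not tell which label is right. A wrong label together with another difference stays open. At resolution 2, PBS 4 gave 2033 of the 2313 nuclei of a DG granule cluster, 850 of the 899 nuclei of a CA2/CA3 cluster and 1018 of the 1117 nuclei of an oligodendrocyte cluster, although at resolution 1 its oligodendrocytes shared cluster 14 with those of the USCs libraries. Of 394 genes under 0.5 times every other library's level in PBS 4, 93.9% overlap a gene on the other strand, against 51.5% of the 12230 genes compared, so a difference in library preparation or counting that lowers reads over such genes is a candidate cause for these genes. Of 71 genes over 2 times every other library's level in PBS 4, 43.7% overlap such a gene, so this cause leaves their difference unexplained. The labels state no batch, and no biological explanation was tested for this library.

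The genes that separate the USCs libraries from PBS 1 to 3 moved PBS 4 as well, to a median position of at least 0.713 in the 7 sets of nuclei. Counting over opposite strands is argued against as the cause, since 49.9% of genes called over all nuclei overlap a gene on the other strand, against 49.5% of genes tested. A preparation difference shared by PBS 4 and the USCs libraries cannot be told apart from other causes. Its test, the position of PBS 4, is the pattern itself, other measures of the libraries pointed different ways, and the labels give no batch. The upper bound on free RNA in microglia set PBS 4 (1.14% of UMIs) apart from the USCs libraries (6.36% to 11.6%). Malat1, at 6.86% of UMIs in PBS 4, lay in their range (5.53% to 6.87%) and below PBS 1 to 3 (7.30% to 8.32%). An effect of the treatment stays open for the differences between the groups.

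Other splits of the 8 libraries into 4 and 4, 35 in all, were tested for gene counts. In 8 sets 1 of 35 splits, the real one, gave as many gene calls: CA1 498 (highest other 0), CA2/CA3 355 (0), DG granule neurons 708 (0), GABA interneurons 126 (6), microglia 187 (0), oligodendrocytes of clusters 8, 33 and 14 239 (0), subicular or cortical neurons 59 (1) and all nuclei 579 (0), by edgeR. This is the lowest share that 35 splits can give, and all sets rest on the same 8 libraries. Chance is therefore less likely as the source of these counts but not excluded. The splits cannot part the treatment from another difference that follows the groups. The splits say nothing about chance in Cajal-Retzius neurons, astrocytes and oligodendrocyte precursors, since any split reaches the real count there, 0 by edgeR (98, 403 and 689 genes at an unadjusted p under 0.05, and 0, 0 and 1 by DESeq2), with 56, 3 and 13 as the highest other and so 35 of 35 splits as many. For lists chance cannot be excluded in the 10 sets with lists called: CA1 6 (highest other 14, 22 splits as many), CA2/CA3 5 (11, 19), DG granule neurons 6 (16, 20), GABA interneurons 2 (13, 35), astrocytes 7 (15, 13), microglia 13 (16, 10), oligodendrocytes 13 (16, 8), precursors 3 (9, 27), subicular or cortical neurons 5 (15, 21) and all nuclei 7 (19, 29). In Cajal-Retzius neurons, with 0 lists by camera (0 at an unadjusted p under 0.05), any split reaches the real count (highest other 2, 35 splits), so the splits say nothing there.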

How the results depend on the processing

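The microglial cluster kept, voom with quality weights and the estimated correlation without PBS 4 were chosen only after the data had been seen. Of the genes called, 2751 of 2751 kept their direction with DESeq2, other size factors, no filter on low counts and voom, 2658 of 2658 with counts thinned, 2158 of 2160 at resolution 2, and 109 of 186 with the microglial cluster kept. DESeq2, other size factors, no filter and voom use the same counts, so kept directions were nearly certain there. Of 192 named genes called, 187 were called with DESeq2, 189 with other size factors, 174 of 184 with at least 1000 genes, 180 with doublets kept, 175 without the filter on low counts, 150 of 153 with the filter on free RNA, 139 of 166 at resolution 2, 144 of 180 with counts thinned, 187 with voom and 0 of 33 with the microglial cluster kept. Without PBS 1, 2, 3 and 4 they were 54, 23, 108 and 192, and without USCs 1, 2, 3 and 4 33, 1, 2 and 1. Where no cause is given below, the cause was not tested.

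With 1 library left out, gene counts ranged from 0 to 3165 in CA1, 0 to 2472 in CA2/CA3, 1 to 4296 in DG granule neurons, 0 to 2003 in GABA interneurons, 0 to 1 in astrocytes, 1 to 445 in microglia, 0 to 1187 in oligodendrocytes (clusters 8, 33 and 14), 0 to 16 in precursors, 0 to 1695 in subicular or cortical neurons, 0 to 0 in Cajal-Retzius neurons and 0 to 4748 over all nuclei, by edgeR. The highest was without PBS 4 in each of these except astrocytes, where it was without USCs 2, and Cajal-Retzius neurons. Lists ranged from 5 to 9 in CA1, 1 to 6 in CA2/CA3, 0 to 2 in Cajal-Retzius neurons, 1 to 6 in DG granule neurons, 0 to 4 in GABA interneurons, 1 to 10 in astrocytes, 11 to 16 in microglia, 7 to 14 in oligodendrocytes, 2 to 8 in precursors, 5 to 11 in subicular or cortical neurons and 5 to 9 over all nuclei, by camera.

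Differences in shares, in percentage points and none past the threshold, ranged from -2.10 to -0.713 in CA1, -1.53 to -0.238 in CA2/CA3, -0.110 to -0.0288 in Cajal-Retzius neurons, -3.64 to 1.43 in DG granule neurons, -0.122 to 0.0247 in mossy cells, -1.91 to -0.477 in GABA interneurons, -0.969 to -0.374 in astrocytes, -0.167 to -0.0336 in choroid plexus epithelium, -0.143 to 0.0525 in fibroblasts, 0.343 to 0.833 in microglia, 1.19 to 4.57 in oligodendrocytes, -0.571 to -0.282 in precursors, -0.134 to -0.0191 in perivascular macrophages and -2.19 to -0.451 in subicular or cortical neurons. The sign reversed in DG granule neurons without PBS 1 (1.43), PBS 4 (0.182) or USCs 2 (0.948), in mossy cells without PBS 4 (0.0247) or USCs 4 (0.00299) and in fibroblasts without PBS 3 (0.0525). It reversed for perivascular macrophages with at least 1000 genes (0.0183), and on the centred log-ratio for CA1 (0.0428), Cajal-Retzius neurons (0.0293), DG granule neurons (0.145) and fibroblasts (0.0672).

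DESeq2 called 1106 genes in CA1, 628 in CA2/CA3, 1468 in DG granule neurons, 345 in GABA interneurons, 497 in oligodendrocytes of clusters 8, 33 and 14, 1 in precursors, 306 in subicular or cortical neurons and 2220 over all nuclei. Voom with quality weights called 3046, 2228, 3996, 1814 and 969 in the first 5 of these, 1536 in subicular or cortical neurons and 4944 over all nuclei. It gave PBS 4 a low weight, 0.110 in CA1. Without the filter on low counts, where more genes are tested, the counts were 4 in Cajal-Retzius neurons, 50 in astrocytes, 527 in microglia, 700 in oligodendrocytes, 88 in precursors and 208 in subicular or cortical neurons, and lists 6 in GABA interneurons, 5 in precursors and 8 in subicular or cortical neurons. With at least 1000 genes per nucleus, oligodendrocytes had 469 genes and astrocytes 3 lists. With doublets kept, subicular or cortical neurons had 92 genes and astrocytes 4 lists. At resolution 2, microglia had 89 genes, precursors 1 and subicular or cortical neurons 107. With counts thinned, which leaves fewer counts per library, microglia had 71 and oligodendrocytes 52.

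With an estimated correlation, camera called 0 lists in every set of nuclei, with or without PBS 4. At an unadjusted p under 0.05 there were 0 to 3 lists in each with an estimated correlation, and 0 to 6 without PBS 4.

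With the microglial cluster kept that had many marked nuclei, edgeR called 0 genes (356 at an unadjusted p under 0.05, DESeq2 not run) and camera 5 lists. Of 33 named genes called, 14 kept their direction. The log2 change reversed for 19, among them Sh3rf1 (-0.19), Chrm3 (-0.90), Ncald in microglia (-0.00223), Dlgap1 (-0.26), Grin2a (-0.21), Grm7 (-0.15), Grm5 (-0.18), Rims1 (-0.11), Nrxn3 (-0.56), Syn2 (-0.11), Kcnc2 (-0.11), Kcnd2 (-0.16), Kcnq5 (-1.15), Epha6 (-0.55), Epha5 (-0.22), Robo1 (-0.35) and Nrg3 (-0.32).

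The replicate number as a block, although the labels state no pairing, gave by edgeR 0 genes in CA1, CA2/CA3, DG granule neurons, subicular or cortical neurons and all nuclei (2780, 2468, 2992, 2051 and 3707 at an unadjusted p under 0.05, DESeq2 not run), 1 in GABA interneurons, 123 in microglia, 34 in oligodendrocytes and 2 in precursors. Of 192 named genes called, 28 were called with the block, and 192 kept their direction, which the same counts made nearly certain. Lists with the block were 1 in Cajal-Retzius neurons, 6 in GABA interneurons and 8 in subicular or cortical neurons.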

Other observations

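The test of glucocorticoid exposure was chosen only after the result was seen, and the tests of free RNA and doublets were written before their values were seen.

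Synaptic, channel and axon guidance genes were called higher in microglia of the USCs libraries. Doublets of a microglial and a neuronal nucleus are argued against only among the nuclei used. There the median percent of UMIs from the 5 lists per nucleus rose by 97.4% of the rise of the mean. Marked nuclei and the microglial cluster with many of them had been left out before, so the test could not show their effect. With that cluster kept, 0 of 33 named genes were still called and 19 reversed, so the calls depended on leaving it out. Free RNA stays open as a cause, since an upper bound on it gave a median of 69.6% of the rise of 26 genes. The bound cannot show that free RNA was the source. It rests on genes abundant over all nuclei, and a real rise of neuronal genes in microglia would raise it as well. Grin2a and Nrxn3 were lowest in PBS 4 (76.2 and 152 CPM), where the bound was 1.14% of UMIs against 4.36% to 6.14% in the other PBS libraries. A change of expression in microglia stays open and was not tested.

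Glucocorticoid response genes differed between PBS libraries in oligodendrocytes, with Fkbp5 at 95.5, 657, 465 and 196 CPM in PBS 1 to 4, in clusters 8 (PBS 1), 33 (PBS 2 and PBS 3) and 14 (PBS 4). Glucocorticoid exposure that differed between animals may be 1 explanation, since the list's score in oligodendrocytes and DG granule neurons had r = 0.836 over 8 libraries (adjusted p = 0.0444 by an exact permutation test). It cannot be told apart from other differences of PBS 2 and PBS 3, since r was 0.399 without them and 7 of 34 lists had an r as high.

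Genes called in at least 4 classes were 47 in 4, 25 in 5, 4 in 6 and 2 in 7. Banp was higher in 7 and 2210408I21Rik lower in 7, and Ctso, Mrps26, Tmem165 and Zc3h6 were lower in 6 (Banp, Mrps26 and Zc3h6 overlap an annotated gene on the other strand). Cirbp was at 23.3 ± 1.53 and 12.9 ± 2.58 CPM in DG granule neurons, and Rbm3 at 104 CPM there in PBS 4 and at 34.0 to 45.8 CPM in the other PBS libraries. Cluster 20, without a class name, held 1.08% of PBS and 3.24% of USCs nuclei (p = 0.171), and cluster 22 held 1.92% and 4.93% (p = 0.0857), both at an adjusted p of 0.386 by the exact permutation test.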
